A study of Mus musculus with 7 samples.

How the data were processed

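Total RNA from 7 liver samples of mice was sequenced, 1 library per sample. The authors deposited a table of FPKM (fragments scaled by transcript length and by the number of mapped fragments) with a column for each library, per the file headers. Per the submitters' processing notes the tools were cutadapt 1.9, FastQC 0.11.9, HISAT2 2.2.1 and StringTie 2.1.6, and the builds GRCm38 and mm10 were named; the notes used here give no role or order for them. How strand was handled is not given in the sources used here. The table listed 27810 genes, each above 0 in at least 1 library. The FPKM values were not whole multiples of the value of 1 read, so reads could not be recovered, the depth is unknown and no counting interval is given. A planned count test was not applicable for this reason. FPKM is a share of each library, so a few abundant transcripts taking a larger share lower the values of all other genes. StringTie divides reads among overlapping transcripts and near-identical copies, so values of genes in tandem families or on the same strand as another gene are uncertain.

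Coordinates are those of the deposited table. Gene types and same-strand overlaps came from the GENCODE annotation of GRCm38. Of the gene identifiers, 99.75% matched it, and 89.86% of the matched genes had the same start and end in the deposited table.

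Groups followed the labels: 3 MSC libraries, 3 vehicle libraries and 1 vehicle library whose label holds the word Cancer. Values were analysed as log2(FPKM + 1), so a log2 difference understates the change of low genes. For MSC minus vehicle, genes with at least 1 FPKM in at least 3 of the 6 libraries were tested with limma (lmFit and eBayes with trend), with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. The Cancer-labelled library was compared with the 3 vehicle libraries in a limma model of 3 groups over all 7 libraries, for genes with at least 1 FPKM in 3 libraries or in that library. Its spread came from the other libraries.

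Gene lists were tested with limma's camera at a preset correlation of 0.01, for 43 lists of pathways, cell type markers and tissues, 41 of which had at least 4 tested members. Camera with an estimated correlation and fry were run beside it. Members were also counted with p-values adjusted over the list alone. For the Cancer-labelled library, each list's median log2 difference was set against 10000 random lists of the same size matched on mean expression, and lists outside the central 95% were described. The 5 genes of the title were tested in addition by an exact two-sided permutation of 3 against 3 libraries, whose smallest p is 0.1.

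The groups, tests, gene lists and the rule for named genes were chosen before the data were examined, as were most alternatives. The rule names the 5 title genes. It also names, among genes past the threshold with a mean of at least 2 FPKM and no overlap between the groups, the 12 with the largest positive and the 12 with the largest negative difference; where fewer than 12 passed, a direction was filled to 6 with the genes of lowest p. From each list that passed, and from the lists of PPARα targets, β-oxidation, fatty acid synthesis, collagens, cytokines and recruited macrophages in any case, it takes up to 4 members of lowest p. It leaves out identifiers, immunoglobulin and T-cell receptor segments and pseudogenes. Some genes that the rule names are not reported here.

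Alternatives covered the pseudocount (0.1 and 5), the filter on low values, the scaling of libraries (TPM, median centring, quantile normalization), limma settings, the place of the Cancer-labelled library and leaving out each library in turn. Removal of mitochondrially encoded genes, joint removal of MSC replicate 0 and vehicle replicate 1, KEGG pathways and the alternatives for the Cancer-labelled library's lists and for correlations were added after seeing the data.

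The limma steps were tested on simulated data with 200 changed genes. Noise was drawn independently for each gene, so the variation that genes share in the real libraries was absent. The recovery below is therefore a check of the steps and does not measure power in these data. For MSC minus vehicle (10534 genes), 55 of 100 genes changed by a log2 of 1 and 93 of 100 changed by 2 were recovered, with 10 wrong calls among 158. For the Cancer-labelled library (12265 genes), 5 of 100 and 66 of 100 were recovered, with 2 wrong calls among 73. Software was R 4.3.3 with limma 3.58.1, jsonlite 2.0.0 and the package data.table (version 1.17.8), and figures used matplotlib 3.10.9 and pandas 2.3.3.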

Results

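Bulk RNA sequencing measured gene expression in 7 liver samples from male C57BL/6J mice kept from 5 weeks of age on a diet rich in fat, fructose and cholesterol. The labels call this diet WD and the condition it produces NASH, a fatty liver disease with inflammation (steatohepatitis). By the labels the diet held 40% fat, 20% fructose and 2% cholesterol. After 32 weeks of feeding, each mouse received 1 tail-vein injection of either saline (vehicle) or mesenchymal stromal cells (MSCs) from human umbilical cord, and tissue was taken after 40 weeks. The MSC group held 3 libraries (replicates 0, 1 and 2) and the vehicle group 3 (replicates 1, 3 and 4). A further vehicle library, replicate 6, carried the word Cancer in its label and was kept apart as a group of 1. The labels do not say what that word refers to in the sampled tissue. The labels do not say outright that each library came from a separate animal, so the p-values measure the spread between these libraries.

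The table listed 27810 mouse genes in FPKM, a length- and depth-scaled expression value. It held no read counts, so the depth of each library is unknown. Between 9655 and 12041 genes reached 1 FPKM per library, the most in the Cancer-labelled library. Mitochondrially encoded genes took 16.5% to 23.3% of the summed FPKM in 6 libraries and 36.4% in MSC replicate 1. The major urinary proteins, abundant secreted products of male mouse hepatocytes, took 17.0% in MSC replicate 2 and 2.195% in the Cancer-labelled library. Pearson correlations of log2 values were 0.960 to 0.969 within the MSC group, 0.968 to 0.977 within the vehicle group and 0.948 to 0.977 between those groups. The Cancer-labelled library correlated at 0.928 to 0.946 with the vehicle libraries. It stood apart on the leading principal component, which held 46.4% of the variance. No pair of libraries was identical, and the median absolute log2 difference between any pair was at least 0.165.

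The first comparison asked what differed between livers of MSC-injected and vehicle-injected mice, and the series title names 5 genes as lower: Acot1, Acot2, Acot3, Cyp4a10 and Cyp4a14. All 5 were lower in each MSC library than in each vehicle library, by ratios of group means between 3.07 and 5.07. Acot1 and Acot2 encode thioesterases that release free fatty acids from acyl-CoA, in cytosol and mitochondria, and Acot3 encodes a peroxisomal member of the same family. Cyp4a10 and Cyp4a14 encode microsomal fatty acid omega-hydroxylases, classical targets of the nuclear receptor PPARα. Acot1 measured 11.7 ± 6.58 FPKM in MSC livers and 48.5 ± 16.7 in vehicle livers (SD, n = 3 each). Acot2 measured 13.4 ± 1.06 and 41.2 ± 11.6 FPKM, and Acot3 11.5 ± 3.12 and 58.3 ± 31.5 FPKM (SD, n = 3 each). Cyp4a10 measured 211 ± 101 FPKM against 794 ± 270, and Cyp4a14 205 ± 19.9 against 760 ± 409 (SD, n = 3 each). The Cancer-labelled vehicle library held Acot1 at 40.1, Acot2 at 38.3, Acot3 at 30.1, Cyp4a10 at 762 and Cyp4a14 at 806 FPKM.

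**Figure D1:**
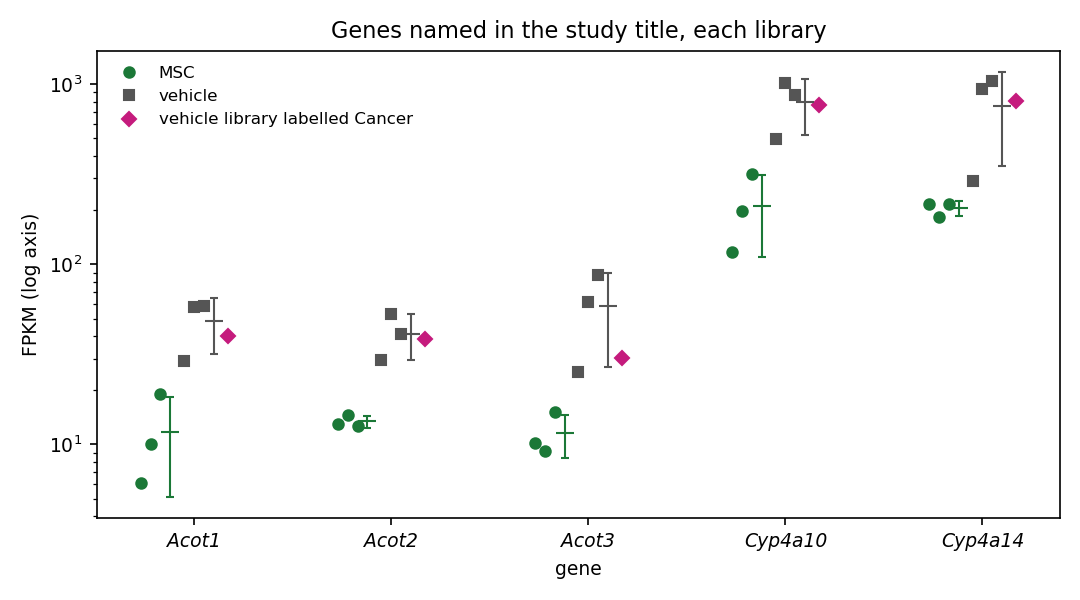
FPKM of the 5 genes named in the study title (log axis) in each library of the MSC group, the vehicle group and the Cancer-labelled vehicle library. Points are libraries, and the short bars with whiskers give mean ± SD of the groups of 3. Each MSC point lies below each vehicle point of the same gene.

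The log2 difference, MSC minus vehicle on log2(FPKM + 1), was -2.02 ± 0.40 for Acot1, -1.51 ± 0.23 for Acot2, -2.10 ± 0.41 for Acot3, -1.96 ± 0.42 for Cyp4a10 and -1.69 ± 0.46 for Cyp4a14 (SE). None of the 5 passed in limma over all 10534 genes tested, with adjusted p from 0.235 to 0.624. All 5 passed adjusted over the list alone, with adjusted p from 0.000572 to 0.00596. The study named these genes from the same samples, so that count is not independent evidence. The exact two-sided permutation test gave p = 0.1 for each gene, the smallest value 3 against 3 libraries allow. Acot1 (ENSMUSG00000072949), Acot2 (ENSMUSG00000021226) and Acot3 (ENSMUSG00000021228) lie within a tandem cluster on chromosome 12 of GRCm38, at 84009490-84018371, 83987861-83993873 and 84052144-84060402. Cyp4a10 (ENSMUSG00000066072, 115518264-115533649) and Cyp4a14 (ENSMUSG00000028715, 115486200-115496142) lie in a cluster on chromosome 4. Close copies in such clusters can share reads, so sums were also taken: Acot1 to Acot6 summed to 56.9 ± 7.82 FPKM in MSC and 188 ± 61.2 in vehicle libraries, and 6 listed Cyp4a members to 527 ± 121 and 1781 ± 739 (SD, n = 3 each). Vehicle replicate 1 lay nearest to the MSC libraries for all 5 genes, and without it Acot2 (adjusted p = 0.0415) and Acot3 (adjusted p = 0.0225) passed in limma over all genes. None of the 5 passed over all genes without any other single library. The limma adjusted p ran from 0.444 to 0.978 without vehicle replicate 3 and from 0.919 to 0.9999 without vehicle replicate 4.

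Of the 30 other PPARα targets tested, 27 had a negative difference, and 14 passed adjusted over the list alone, all lower in MSC livers. The list as fixed includes Acot4, Acot5, Cyp4a12a, Cyp4a31 and Cyp4a32, from the same gene families as the title genes. Reads can be shared within these families, so the list is not fully separate from the title genes. Crat, carnitine acetyltransferase, measured 12.9 ± 0.645 FPKM in MSC and 32.0 ± 6.68 in vehicle libraries, and Ehhadh, the peroxisomal bifunctional enzyme of β-oxidation, 188 ± 59.8 and 768 ± 279 (SD, n = 3 each). Acot4, a peroxisomal thioesterase, measured 19.8 ± 1.30 and 38.7 ± 6.73 FPKM, and Slc27a1, a fatty acid transporter, 1.56 ± 0.353 and 3.53 ± 0.543 (SD, n = 3 each). None of these 4 passed over all genes (adjusted p from 0.273 to 0.450 in limma). The list's median log2 difference was -0.79, with a camera adjusted p of 7.26e-16 at the preset correlation. The adjusted p was 0.340 with an estimated correlation. Fabp1, Fabp2 and Angptl4 were the members with a positive difference, at 0.17, 0.00 and 0.08 on the log2 scale, and Ppara itself measured 21.6 against 29.01 FPKM.

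Mitochondrial and peroxisomal β-oxidation genes showed 29 of 31 members with a negative difference (median log2 -0.34; camera adjusted p = 1.39e-07; adjusted p = 0.363 with an estimated correlation). None of the 31 passed adjusted over the list alone. The members with the lowest p were Abcd3, a peroxisomal fatty acyl-CoA transporter (65.3 ± 11.5 against 116 ± 3.57 FPKM), Cpt2, an inner-membrane carnitine palmitoyltransferase (43.2 ± 7.24 against 68.8 ± 7.46), and Hsd17b4, a peroxisomal multifunctional enzyme (88.8 ± 12.4 against 142 ± 12.6; SD, n = 3 each). Other acyl-CoA synthetases and thioesterases had 12 of 16 members lower and 1 past the threshold adjusted over the list alone (median log2 -0.23; camera adjusted p = 0.00132; adjusted p = 0.363 with an estimated correlation). That member was Acss3, a mitochondrial short-chain synthetase (2.04 ± 0.384 against 5.36 ± 1.40 FPKM), and Acot12 measured 30.8 ± 1.26 against 43.9 ± 1.45 (SD, n = 3 each). This list's adjusted p was 0.0536 without MSC replicate 0, 0.0601 with the Cancer-labelled library among the vehicle libraries and 0.106 without MSC replicate 0 and vehicle replicate 1, and its median was -0.35 as TPM. Among lipid droplet proteins, 14 of 16 were lower and 3 passed adjusted over the list alone (median log2 -0.47; camera adjusted p = 3.76e-06; adjusted p = 0.363 with an estimated correlation). Fitm2, which promotes droplet formation, measured 19.8 ± 2.63 against 39.6 ± 5.26 FPKM, and Plin5, a droplet coat protein, 18.7 ± 6.46 against 36.0 ± 5.52 (SD, n = 3 each). Without vehicle replicate 4 the lipid droplet median was -0.71. Fatty acid synthesis and desaturation genes did not pass (adjusted p = 0.552): 16 of 30 members were lower and 14 higher, with a median of -0.02 and a mean of -0.07 while the camera test pointed up. Elovl3, a fatty acid elongase, measured 13.5 ± 12.99 against 58.6 ± 34.7 FPKM, Acacb 10.1 ± 3.21 against 15.0 ± 5.33 and Agpat2 48.4 ± 6.86 against 63.8 ± 12.6 (SD, n = 3 each).

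Genes that mark hepatocytes around the central vein were lower as a list: 17 of 19 had a negative difference and 6 passed adjusted over the list alone (median log2 -0.51; camera adjusted p = 1.32e-07; adjusted p = 0.363 with an estimated correlation). Oat, ornithine aminotransferase, measured 119 ± 34.6 against 363 ± 49.6 FPKM, and Slc1a2, a glutamate transporter, 6.50 ± 3.92 against 17.0 ± 0.803 (SD, n = 3 each). In the Cancer-labelled library, Oat was at 89.7 and Slc1a2 at 2.86 FPKM, and with that library counted among the vehicle libraries the list's adjusted p was 0.0906. Without MSC replicate 0 and vehicle replicate 1 it was 0.0531. Periportal hepatocyte genes, their counterpart, did not pass (median log2 -0.24; adjusted p = 0.267). Drug and xenobiotic metabolism had 35 of 39 members lower and none past the threshold over the list alone (median log2 -0.42; camera adjusted p = 9.04e-07; adjusted p = 0.363 with an estimated correlation). Ugt2b35, a glucuronosyltransferase, measured 29.02 ± 0.394 against 54.1 ± 8.56 FPKM, and Fmo1, a flavin monooxygenase, 20.5 ± 1.92 against 33.5 ± 4.39 (SD, n = 3 each). The list's adjusted p was 0.0866 without MSC replicate 0 and vehicle replicate 1.

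NRF2 and oxidative stress genes were lower in 21 of 22 cases (median log2 -0.29; camera adjusted p = 0.000725; adjusted p = 0.363 with an estimated correlation). Hmox1, haem oxygenase, measured 9.38 ± 4.55 against 28.0 ± 17.7 FPKM and Txnrd1, thioredoxin reductase, 12.4 ± 2.48 against 18.3 ± 2.43 (SD, n = 3 each). Heat shock genes were lower in 12 of 18 cases (median log2 -0.32; camera adjusted p = 0.00272; adjusted p = 0.430 with an estimated correlation), with Bag3, an HSP70 co-chaperone, at 5.92 ± 0.643 against 9.56 ± 1.10 FPKM and Dnaja1 at 19.3 ± 3.64 against 30.6 ± 1.96 (SD, n = 3 each). The list for pancreas, muscle and blood passed with 5 of 5 members lower (median log2 -1.82; camera adjusted p = 9.26e-06; adjusted p = 0.363 with an estimated correlation). Those members were 4 haemoglobin genes and Alas2, the erythroid haem synthesis enzyme, transcripts carried by red cells. Hba-a2 measured 28.7 ± 12.8 against 116 ± 71.4 FPKM and Hbb-bs 48.7 ± 23.4 against 201 ± 122 (SD, n = 3 each), with 213 FPKM of Hbb-bs in the Cancer-labelled library. This list's median was -0.12 without the filter on low values and -2.75 without MSC replicate 0 and vehicle replicate 1.

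Unfolded protein and integrated stress response genes went the other way: 21 of 27 were higher in MSC livers and 4 passed adjusted over the list alone (median log2 0.30; camera adjusted p = 2.92e-10; adjusted p = 0.363 with an estimated correlation). Manf, a secreted factor of the endoplasmic reticulum stress response, measured 13.4 ± 2.96 against 5.32 ± 1.82 FPKM, and Sdf2l1, an endoplasmic reticulum chaperone component, 15.9 ± 3.92 against 5.54 ± 3.18 (SD, n = 3 each). The median of this list was 0.59 without MSC replicate 2, 0.45 without vehicle replicate 1, 0.44 without vehicle replicate 3 and 0.46 at a pseudocount of 0.1. Cholesterol synthesis and LDL uptake genes were higher in 20 of 24 cases (median log2 0.31; camera adjusted p = 3.96e-05; adjusted p = 0.732 with an estimated correlation). Its member with the lowest p, Hsd17b7, was lower (5.04 ± 0.428 against 8.30 ± 1.27 FPKM; SD, n = 3 each). The list's score was higher in vehicle replicate 1 (3.66) than in each MSC library (3.196 to 3.4), and its median was 0.66 without that library, 0.197 without MSC replicate 1, 0.18 without vehicle replicate 3, 0.17 at a pseudocount of 5 and 0.03 without vehicle replicate 4 (adjusted p = 0.0120 for the last). It was 0.75 without MSC replicate 0 and vehicle replicate 1. Immediate early genes were higher in 15 of 19 cases (median log2 0.35; camera adjusted p = 9.99e-05; adjusted p = 0.514 with an estimated correlation). Zfp36 measured 24.8 ± 3.63 against 16.5 ± 7.23 FPKM and Ier2 8.78 ± 2.57 against 5.85 ± 1.79 (SD, n = 3 each). The immediate early median was 0.21 without MSC replicate 0, 0.18 without vehicle replicate 4, 0.1996 without MSC replicate 0 and vehicle replicate 1, and 0.03 with the Cancer-labelled library among the vehicle libraries (adjusted p = 0.0460). Cytosolic ribosomal proteins were higher in 36 of 41 cases (median log2 0.13; camera adjusted p = 9.20e-05; adjusted p = 0.898 with an estimated correlation), with Rpl38 at 72.0 ± 20.8 against 52.6 ± 14.9 FPKM and Rps29 at 71.2 ± 21.2 against 53.2 ± 17.9 (SD, n = 3 each). The ribosomal median was 0.06 without MSC replicate 1, 0.03 without vehicle replicate 4, 0.24 without vehicle replicate 3, 0.05 with the Cancer-labelled library among the vehicle libraries, 0.03 as TPM and 0.2024 with quantile normalization. Mitochondrially encoded transcripts were higher in 13 of 13 cases (median log2 0.30; camera adjusted p = 0.0117; adjusted p = 0.898 with an estimated correlation), with mt-Nd6 at 4380 ± 2936 against 2508 ± 193 FPKM and mt-Nd5 at 3526 ± 2365 against 2200 ± 130 (SD, n = 3 each). The mitochondrial median was 0.64 without MSC replicate 0, 0.56 without MSC replicate 0 and vehicle replicate 1, 0.19 as TPM and 0.03 with quantile normalization. Without MSC replicate 1 the mitochondrial list turned to a median of -0.13 (adjusted p = 0.645) and the ribosomal list gave 0.0595. Without vehicle replicate 1 they gave adjusted p of 0.332 and 0.0874, and the mitochondrial list gave 0.0699 with libraries centred on their medians, 0.147 without the filter on low values and 0.697 with quantile normalization.

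**Figure D2:**
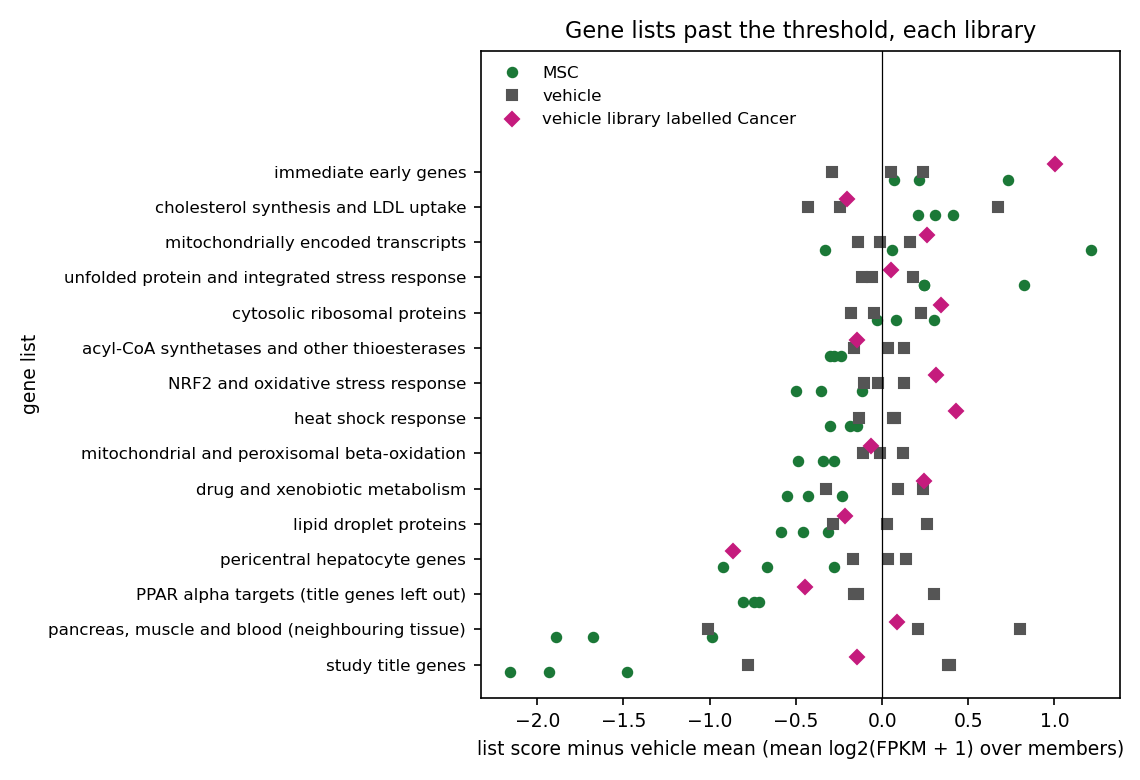
Score of each of the 15 gene lists past the camera threshold (mean log2(FPKM + 1) over its tested members) in each library, minus the mean of the vehicle group. The 3 MSC points and the 3 vehicle points are fully apart for the PPARα targets, with scores of 5.56 ± 0.047 and 6.32 ± 0.261 (SD, n = 3 each), and overlap for the mitochondrially encoded transcripts.

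Scarring and inflammation genes, hallmarks of steatohepatitis, did not pass as lists. Collagens and extracellular matrix genes had 23 of 28 members lower (median log2 -0.24; camera adjusted p = 0.397). Col5a3 measured 3.47 ± 1.42 against 2.01 ± 0.411 FPKM, Dcn 41.6 ± 13.7 against 57.8 ± 12.03, Timp3 4.75 ± 2.15 against 7.87 ± 5.25 and Bgn 18.5 ± 5.34 against 25.5 ± 12.1 (SD, n = 3 each). Lipid-associated and recruited macrophage genes had 15 of 20 lower (median log2 -0.17; adjusted p = 0.432), with Gpnmb at 5.02 ± 2.498 against 7.02 ± 1.92 FPKM, Ctsk at 1.00 ± 0.766 against 1.55 ± 0.388, Cd14 at 5.10 ± 3.07 against 3.37 ± 0.301 and Cd68 at 8.02 ± 3.94 against 9.88 ± 2.64 (SD, n = 3 each). Cytokines and chemokines had 7 of 17 lower (median log2 0.00; adjusted p = 0.352), with Ccl9 at 13.8 ± 2.91 against 10.6 ± 3.10 FPKM, Icam1 at 5.13 ± 2.96 against 3.14 ± 0.516, Ccl3 at 1.67 ± 1.00 against 2.75 ± 1.28 and Il18 at 4.12 ± 0.945 against 5.19 ± 1.01 (SD, n = 3 each). Markers of Kupffer cells (median log2 -0.32), stellate cells (-0.17), sinusoidal endothelium (-0.11), bile duct cells (-0.13), B and plasma cells (-0.09), neutrophils (-0.12) and class II antigen presentation (-0.35) did not pass (adjusted p from 0.0631 to 0.988). MSC replicate 0 and vehicle replicate 1 held the highest matrix scores of their groups, 2.99 and 3.25 against 2.01 to 2.40 in the other 4 libraries. Without MSC replicate 0 the matrix and macrophage lists passed as lower (adjusted p = 0.0110 and 0.00160), and without vehicle replicate 4 the matrix list passed (0.00415), whereas without vehicle replicate 1 its median was 0.09 (0.202). Without MSC replicate 1 the cytokine list passed as higher (0.0259), and fatty acid synthesis passed as higher without MSC replicate 0 (0.0122) or vehicle replicate 1 (0.00490). Without both of these libraries its median was 0.43 (7.69e-06), and recruited macrophages passed as lower (median -0.31; 0.0187).

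Gene by gene, 2 of the 10534 genes passed in limma at an adjusted p under 0.05, and both were picked for mention after their values were seen because the naming rule left them out. Gm20716 was listed at 10.4, 8.16 and 9.77 FPKM in the MSC libraries and at 0 in the other 4 libraries (adjusted p = 8.38e-05). It is an annotated transcription unit on chromosome 2 (168180986-168230364, minus strand of GRCm38) that spans Adnp and Dpm1 on the same strand. Adnp measured 2.24 ± 1.11 against 8.75 ± 1.28 FPKM and Dpm1 1.72 ± 0.444 against 5.68 ± 0.563 (SD, n = 3 each), and both were among the 6 genes of lowest p on the lower side. Mup-ps18, a pseudogene of the major urinary protein family on chromosome 4, was listed at 142, 82.4 and 254 FPKM in the vehicle libraries and at 0 in the other 4 (adjusted p = 8.38e-05). Reads shared with overlapping genes or near-identical copies make both values uncertain.

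Of the remaining genes, those with the lowest p did not pass (adjusted p from 0.182 to 0.473 in limma). On the higher side these were Ptp4a1, a protein tyrosine phosphatase (13.98 ± 2.99 against 2.99 ± 1.58 FPKM), Commd1b (6.26 ± 0.573 against 0.809 ± 1.13), Manf, Arl4d (22.0 ± 0.790 against 12.3 ± 1.43), Spata2l (7.32 ± 1.71 against 2.69 ± 1.23) and Enho, which encodes the secreted peptide adropin (4.25 ± 2.1 against 0.821 ± 0.256; SD, n = 3 each). The Cancer-labelled vehicle library held Ptp4a1 at 4.115, Commd1b at 8.095, Manf at 5.388, Arl4d at 25.7, Spata2l at 4.227 and Enho at 3.145 FPKM, which for Commd1b and Arl4d is above every MSC library. On the lower side they were Dpm1, Acot2, Adnp, Crat, Oat and Entpd5, an endoplasmic reticulum nucleoside diphosphatase (36.3 ± 5.86 against 78.5 ± 1.70; SD, n = 3 each). Ptp4a1, Commd1b, Manf, Oat, Acot3, Acot4, Acss3, Acot12, Abcd3, Hsd17b4, Bag3, Dnaja1 and Txnrd1 overlap another annotated gene on the same strand. At an unadjusted p under 0.05, 153 genes were higher and 436 lower in MSC livers, a split that moved to 309 and 377 when libraries were centred on their medians. Together these were 589 genes. Other divisions of the 6 libraries into 3 and 3 gave from 113 to 1917 genes at this p. The count therefore does not set the division into MSC and vehicle libraries apart. The groups of 3 did not overlap for 1055 genes, or 10.02% of those tested, where chance gives 10%. Without vehicle replicate 1, 9 genes passed, and without vehicle replicate 3, 4 passed. Of 41 lists tested, 15 passed with camera at the preset correlation, 10 lower and 5 higher. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), and with fry 0 passed (8 at an unadjusted p under 0.05). Fry's mixed test, which ignores direction, gave an adjusted p under 0.05 for 8 lists, the PPARα targets (0.01199) and the title genes (0.0433) among them. The title genes were named from these same libraries, so their value is not independent evidence. Fry was not run over other splits of the libraries.

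The second comparison set the Cancer-labelled vehicle library against the 3 vehicle libraries, and it compares that library, not a condition. It held bile duct transcripts at high levels and urinary proteins at low levels. The filter let genes in through a high value in this library, which favours genes that are higher in it. Of the 19 bile duct genes below, 8 also reached the filter over the MSC and vehicle libraries. Of 19 bile duct and ductular reaction genes tested, 16 passed and 0 were lower. Krt19, the keratin of bile duct epithelium, was at 24.4 FPKM where the vehicle libraries held 0.989 ± 0.120 (SD, n = 3), and the tight junction gene Cldn4 at 14.4 against 0.225 ± 0.044. Tspan8 was at 33.0 against 2.23 ± 1.35 FPKM and Cdh1, E-cadherin, at 28.1 against 2.49 ± 1.77. Among tumour and fetal liver genes, 3 of 14 passed as higher, including Tff3, a secreted trefoil peptide (134 against 6.39 ± 0.945 FPKM), and Cd24a (43.9 against 4.06 ± 2.28; SD, n = 3). Mmp7, a matrix metalloproteinase, was at 104 against 3.09 ± 1.73 FPKM and Ankrd1, a target of the YAP coactivator, at 22.4 against 0.578 ± 0.361. Sult1e1, an oestrogen sulfotransferase, was at 34.0 against 2.46 ± 1.21 FPKM. The small noncoding RNAs Rn7s2, Rn7s1 and Rn7s6 were at 103, 55.2 and 8.63 FPKM against 2.73 ± 1.97, 2.51 ± 1.80 and 0.047 ± 0.002 (SD, n = 3). All 3 overlap another annotated gene on the same strand, so their values are uncertain. Rn7s6 was let in through its value in this library.

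Of the genes lower in this library, major urinary proteins led: Mup12 was at 7.50 against 5435 ± 3715 FPKM, Mup19 at 10.1 against 807 ± 508, Mup10 at 31.9 against 1623 ± 811 and Mup3 at 90.6 against 2360 ± 1005 (SD, n = 3). These near-identical copies can share reads, and the 43 listed family members summed to 8781 FPKM in this library and 43260 ± 17060 in the vehicle libraries (SD, n = 3), a smaller fall than that of each of these 4. Colec10, a collectin, was at 0.044 against 7.79 ± 1.82 FPKM. Sult2a8 was at 2.28 against 57.5 ± 19.1 FPKM, Cyp2c37 at 9.53 against 63.3 ± 17.3, Slc1a2 at 2.86 against 17.0 ± 0.803 and Oat at 89.7 against 363 ± 49.6 (SD, n = 3). Dio1, which activates thyroid hormone, was at 16.2 against 57.5 ± 4.88 FPKM, and Cyp8b1, a bile acid 12α-hydroxylase gene, at 24.5 against 85.8 ± 5.804. Angptl6 was at 0.513 against 3.83 ± 0.853 FPKM (SD, n = 3). None of the 5 title genes passed in this comparison.

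Against 10000 random lists of matched size and expression, 13 of the 43 lists lay above the central 95% and 14 below. Random lists lack the co-regulation of real ones, which can place real lists outside more often, and no other library was run this way. Since all genes had a median of 0.25, interferon response (-0.04) and clock genes (-0.005) counted as below with little change. The highest medians were those of bile duct genes (log2 2.14), B and plasma cells (1.56), tumour and fetal liver genes (1.12), immediate early genes (1.01), collagens and matrix (1.00) and female-biased liver genes (0.94). Of the 42 matrix genes tested, 28 also reached the filter over the MSC and vehicle libraries. The same held for 20 of 26 macrophage and 17 of 21 cytokine genes, so these medians include genes let in through this library. The 3 matrix genes that passed averaged under 1 FPKM in both the MSC and vehicle groups, and were let in that way. The matrix list had 3 of 42 members past the threshold, Fbln2 (2.34 against 0.332 ± 0.249 FPKM), Fbln1 (2.37 against 0.419 ± 0.287) and Thbs1 (2.54 against 0.480 ± 0.143), and Mfap4 (3.51 against 0.630 ± 0.650; SD, n = 3) did not pass. Recruited macrophage genes had a median of 0.76 and 1 of 26 members past the threshold, Cd14 (17.1 against 3.37 ± 0.301 FPKM); Lpl (20.2 against 3.92 ± 0.871), Cd9 (35.3 against 11.2 ± 4.80) and Cd63 (21.5 against 4.82 ± 3.33; SD, n = 3) did not pass. Of 21 cytokines and chemokines 3 passed: Ccl2 (13.5 against 0.905 ± 0.414 FPKM), Cxcl16 (20.3 against 3.06 ± 1.42) and Cxcl14 (5.57 against 1.57 ± 0.619), while Ccl7 (1.23 against 0.227 ± 0.217; SD, n = 3) did not. The cytokine list itself lay inside the central range, at the 96.21st percentile (median 0.48), and the macrophage list above it. Stellate cell genes (0.66), class II genes (0.75), periportal genes (0.54), ribosomal proteins (0.36), heat shock genes (0.36) and NRF2 genes (0.30) were the other lists above that range. NRF2 genes lay inside it without vehicle replicate 3 (95.96th percentile) or vehicle replicate 4 (97.18th percentile). The lowest medians were those of male-biased liver genes (-1.59), neutrophils (-1.11), adipocytes (-1.10), pericentral genes (-0.73) and the acute phase response (-0.63). PPARα targets (-0.27) and fatty acid synthesis (-0.37) also lay below the range. From those lists, Cidea was at 2.66 against 44.9 ± 43.1 FPKM, Cyp4a12a at 8.74 against 74.7 ± 62.8, Plin2 at 166 against 310 ± 47.0 and Elovl3 at 6.44 against 58.6 ± 34.7, and Rbp7 passed as higher (1.60 against 0.075 ± 0.129; SD, n = 3). Rbp7 also averaged under 1 FPKM in both the MSC and vehicle groups and was let in through its value in this library. The β-oxidation median of -0.10 lay at the 7.01st percentile, with Acad11 at 27.6 against 42.6 ± 0.586 FPKM and Scp2 at 620 against 949 ± 146 (SD, n = 3). Kupffer cell genes had a median of 0.06, at the 22.3rd percentile.

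**Figure D3:**
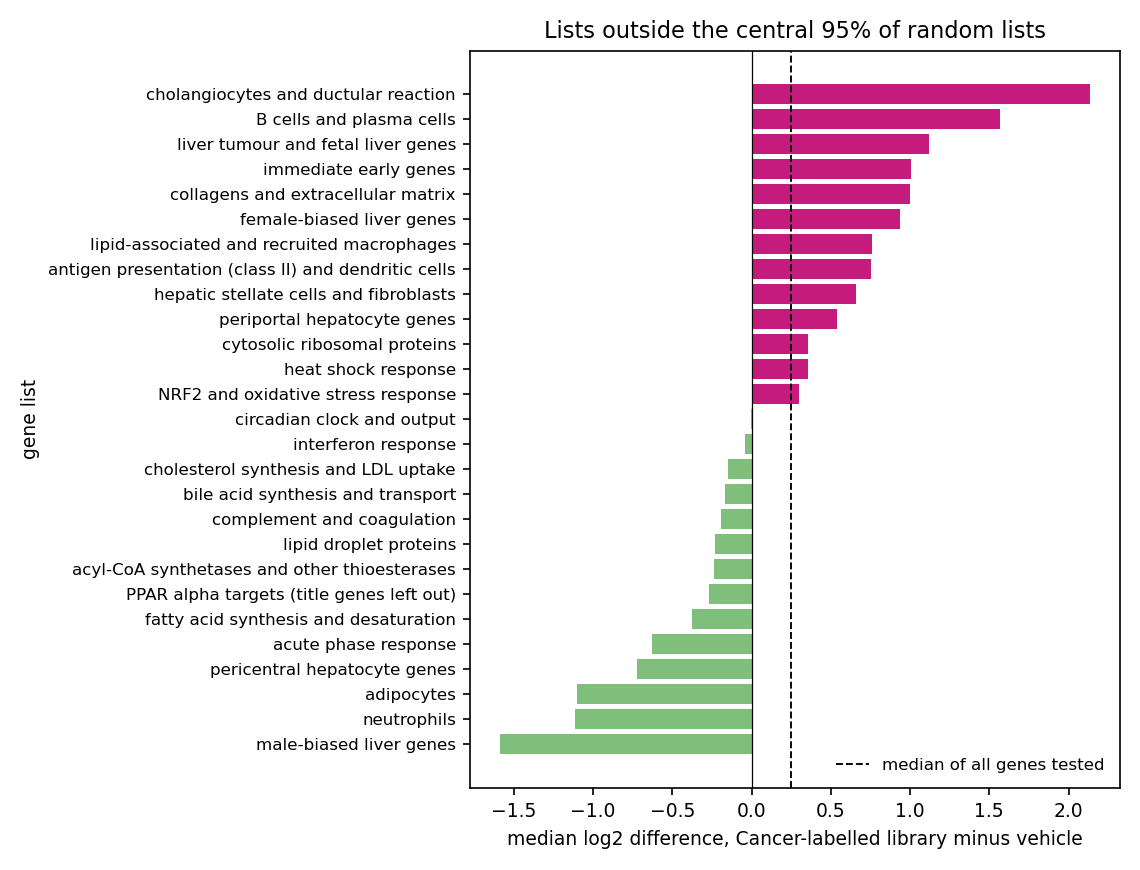
Median log2 difference between the Cancer-labelled library and the 3 vehicle libraries for the 27 gene lists outside the central 95% of random lists. Bars in magenta lie above that range and bars in green below it, and the dashed line marks the median of all genes tested, 0.25.

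In limma over 12265 genes, 488 were higher and 23 lower in this library at an adjusted p under 0.05, 414 and 21 of them protein coding. All genes together had a median log2 difference of 0.25, so differences are read relative to it; quantile normalization took the median to -0.03 and gave 318 higher and 65 lower genes. The count rests on the pseudocount and on the vehicle libraries: a pseudocount of 0.1 left 13 genes (9 higher, 4 lower), without vehicle replicate 3 there were 265 and without vehicle replicate 4 there were 273. Of the 32 named genes past the threshold, 7 passed with that pseudocount and 16 without either of those vehicle libraries, all in the same direction. With 1 library there is no replicate check, and it was assumed to vary like the others. Genes let in through high values in this library also favour the higher side in these counts and in the median of all genes.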

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

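The values with TPM for lists and title genes, without mitochondrial genes, without MSC replicate 0 and vehicle replicate 1 together, and all alternatives for the lists of the Cancer-labelled library and for correlations, were chosen after the data were seen. The depth of the libraries is unknown, so its part in these limits was not tested. No paired analysis was possible because the MSC and vehicle groups share only 1 replicate number. No counts were used, so the planned count tools were not run. Between MSC and vehicle libraries, 2 genes passed under every setting that kept all 6 libraries and these groups; with the Cancer-labelled library among the vehicle libraries 1 passed, because Mup-ps18 is at 0 there. Leaving out each library in turn gave 2 to 9 genes, and 3 passed without MSC replicate 0 and vehicle replicate 1. All 5 title genes passed adjusted over the list alone in each setting run, leave-outs included. They were named from these same libraries, so this is not independent evidence. Of gene lists 15 passed, 14 to 18 under other pseudocounts, filters, scalings or vehicle groups, 18 to 24 without 1 library, 0 with an estimated correlation and 0 with fry. The 15 camera settings kept the PPARα list past the threshold each time, with medians of -0.91 to -0.62, and the β-oxidation list with -0.45 to -0.25. Other lists passed each time with medians that moved more: cholesterol synthesis from 0.03 to 0.75, immediate early genes from 0.03 to 0.489, unfolded protein response from 0.20 to 0.59, lipid droplet proteins from -0.71 to -0.32, and pancreas, muscle and blood from -2.75 to -0.12 (the latter without a filter).

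For the Cancer-labelled library 511 genes passed: 13 with a pseudocount of 0.1, 838 with a pseudocount of 5, 1035 without a filter, 316 as TPM, 286 without mitochondrial genes, and 265 to 588 without 1 vehicle library. Its 27 lists outside the central range became 25 to 28 under other pseudocounts and scalings and 27 to 32 without 1 library. Lists that came inside the range were bile acid synthesis and complement under quantile normalization or without vehicle replicate 4, cholesterol synthesis, interferon response and clock genes without vehicle replicate 1, and NRF2 genes without vehicle replicate 3 or 4. Its mean correlation with the vehicle libraries was 0.937, with 0.906 at a pseudocount of 0.1 and 0.948 at 5.

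Directions turned for results that had not passed or rested on 1 library, and the cause was not tested. Cd14 was at a log2 of -0.15 with the Cancer-labelled library among the vehicle libraries and at -0.0178 to 0.677 without 1 library; mt-Nd5 ranged from -0.0256 to 0.784. List medians without 1 library ranged from -0.13 to 0.64 for mitochondrially encoded transcripts (negative without MSC replicate 1), -0.20 to 0.30 for fatty acid synthesis, -0.573 to 0.0930 for matrix genes (positive without vehicle replicate 1), -0.23 to 0.26 for cytokines (negative without MSC replicate 0) and -0.472 to -0.0311 for recruited macrophages. For recruited macrophages without MSC replicate 1 or vehicle replicate 1, and for matrix genes without MSC replicate 2 (median -0.00399), only the direction given by camera turned. With fry the fatty acid synthesis list, median -0.0165, pointed down where camera pointed up. That list passed as higher (adjusted p = 0.00472 in limma's camera) with the Cancer-labelled library among the vehicle libraries.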

Other observations

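The camera test of the clock list was chosen before the data were examined. So were the counts of genes and lists over other splits of the libraries and that of title genes over the splits of 3 against 3. All other tests in this part were chosen after the result was seen. The clock list did not pass (median log2 0.06; camera adjusted p = 0.232 in limma), with members going both ways. Dbp, a transcription factor whose liver level follows the time of day, was at 21.2, 31.2 and 14 FPKM in the MSC libraries, 14.5, 1.63 and 4.53 in the vehicle libraries and 1.39 in the Cancer-labelled library. Cry1, a clock repressor, was at 1.18, 1.21 and 2.27 FPKM in the MSC libraries and 3.05, 5.36 and 3.55 in the vehicle libraries. An index of 3 genes on each side of the cycle was 2.72 ± 0.508 in MSC and 0.750 ± 1.03 in vehicle libraries (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible).

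Among genes higher in the Cancer-labelled library, 33 of 296 KEGG pathways were enriched. Extracellular matrix receptor interaction held 12 of its 48 tested genes where 1.85 were expected (adjusted p = 4.52e-05), Hippo signalling 16 of 104 where 4.003 were expected (adjusted p = 0.000187) and focal adhesion 19 of 146 where 5.62 were expected (adjusted p = 0.000187). The test treats genes as independent and describes this library alone. Its higher genes and its background both include genes let in through high values in this library. In MSC minus vehicle, 25 of 292 KEGG pathways passed with camera in limma, 19 lower and 6 higher, and 0 passed with an estimated correlation.

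Chance was weighed by counting other splits of the libraries. The 10 splits of 3 against 3 are too few for a share under 0.05. Genes past the threshold numbered 2 in the real split and at most 2 in the others, and 2 of the 10 splits reached that number. Gene lists numbered 15 in the real split and up to 21 in another, and 6 of the 10 splits gave as many. Title genes numbered 5 in the real split and at most 4 in the others, so 1 of the 10 gave as many. With the Cancer-labelled library among the vehicle libraries, chance could not be excluded: 5 of 35 splits gave at least the real count of 1 gene (highest other 3), 16 of 35 gave at least the real 18 lists (highest other 25), and 2 of 35 gave the real 5 title genes (highest other 5). The study named the title genes from these libraries, which favours the real split in that count.

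The values of Gm20716 and Mup-ps18 may reflect how reads were divided among loci. Summed over Gm20716, Adnp and Dpm1, FPKM differed by -1.02 between the groups, within the spread of 1.54. The near equality of the sums goes with reads of overlapping genes assigned differently between libraries. For Mup-ps18, 3 other loci of the family (Mup5, Mup-ps17 and Mup-ps21) were also at 0 in at least 1 library and at 10 FPKM or more in another. Mup-ps17 was at 0 only in the Cancer-labelled library. The zeros of Mup5 and Mup-ps21 fell in both the MSC and vehicle groups, so none of these loci divided by group as Mup-ps18 did. A biological difference between the groups stays open for both, untested.

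For the lower PPARα targets, the tables argue against scaling of the libraries, since the list's median relative to all genes was -0.66 on the log2 scale under quantile normalization. They argue against a lower share of all hepatocytes alike, since 51 secreted hepatocyte genes, from the apolipoprotein and complement lists, had a median of 0.03. That lay 0.82 above the median of the list. Other hepatocyte lists had negative medians: pericentral -0.51, drug metabolism -0.42, bile acid -0.25 and periportal -0.24. The acute phase list, left out of the 51 genes, had 24 of 32 members lower and a median of -0.20. A change in the share of some hepatocytes, such as pericentral ones, is therefore not covered. The time of day at sacrifice could contribute: with the clock index in the fit the score difference was -0.44, against -0.75 without it, and no error of that fit was taken. The Cancer-labelled vehicle library, outside that fit, had the lowest index (-0.783), and its score of 5.87 lay below those of the 3 vehicle libraries (6.16 to 6.62). It is 1 library that differs from them in many other lists, so it cannot test this relation. The index was built after the values were seen and its p is one that 10.02% of all genes reach, so a difference in time of day is itself not established, and its part stays open.

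For the ductal genes of the Cancer-labelled library, scaling is argued against by a ductal median 1.87 above that of all genes on the log2 scale under quantile normalization. A lower hepatocyte share alone would raise the markers of other cell types alike, and the ductal median lay 2.07 above that of Kupffer cell genes. Other cell types were spread widely: B and plasma cells had a median of 1.56, recruited macrophages 0.76, stellate cells 0.66, sinusoidal endothelium 0.45 and neutrophils -1.11. The comparison with Kupffer cells alone therefore does not settle the hepatocyte share. The ductal median also includes genes let in through their value in this library, as does the matrix median below. For the matrix genes neither is settled, with a median 0.76 above that of all genes under quantile normalization and 0.94 above that of Kupffer cell genes. Set alone against the other 6, this library gave 778 genes past the threshold in limma and each of the others 0, so 1 of 7 libraries gave as many, which is too few choices for a share under 0.05. That contrast was also tilted in advance, because the genes were chosen partly by their values in the Cancer-labelled library. Whenever another library was set alone, this outlying library stood among the rest and widened the spread. A candidate explanation for the ductal genes is more bile duct or tumour epithelium in this piece of liver, which was not tested.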
